A study of Homo sapiens with 44 samples.

How the data were processed

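The series holds 44 samples of 2 human cell lines: 24 RNA samples of A549 cells, 16 RNA samples of HEK293-GR cells (HEK293 cells that constantly express the glucocorticoid receptor) and 4 ChIP samples of IRF2BP2 in HEK293-GR cells. Groups were taken from the sample labels. RNA samples differed in the small interfering RNA (siNON or siIRF2BP2, 20 nM, 72 h) and the 6 h treatment (vehicle, 100 nM dex, and in A549 also 10 ng/ml TNF or both), and ChIP samples in 1 h of vehicle or dex. The labels number 4 replicates per HEK293-GR group, while the deposited table has columns for replicates 1 to 3, so 4 samples were not analysed here.

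Per the submitters' processing notes, RNA reads were processed with FastQC, Trimmomatic 0.33, HOMER, Bowtie2, TopHat2 and edgeR, and ChIP reads with FastQC, Bowtie 0.12.9, HOMER 4.10.3 and bedtools, on build hg19, with no order or role given. Per the file headers the expression values are FPKM, which the authors scaled by a length column and the tags of each column before deposit. In the HEK293-GR table (25690 genes) that length is the exon length and each library has its own column, while in the A549 table (48118 transcripts, 25689 symbols) it equals the genomic span in 98.9% of transcripts and the authors pooled the replicates of a group into 1 column. The deposited log2 fold changes were computed by the authors, for the second named group over the first, and the direction was checked against the FPKM. The deposited p-value and FDR columns come from the authors' comparisons, in the form edgeR writes, and the test used is not stated. The score in the deposited peak files is 1 for every peak, so only positions were used, and the files do not say how the replicates and the input were combined.

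Before the data were examined, the tests were planned for read counts, but the files hold FPKM, so limma on the log scale was used instead. Among HEK293-GR values FPKM times length was a whole number of reads, within 0.01 reads beyond rounding, for at least 99.9% of the genes checked in each library, which gave the tags per library: 18.2 to 28.5 M (median 21.1 M), of which 55.6 to 61.7% lay on the genes of the table. The densest gene had 2.83 to 3.11 reads per base across the HEK293-GR libraries, so dense genes lay near a common upper level. The pooled A549 columns had 35.8 to 56.9 M tags, and the reads on the transcripts came to 234 to 236% of them, since overlapping transcripts share reads.

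HEK293-GR genes with at least 10 reads in at least 3 libraries (15593) were tested with limma 3.58.1 (trend) in R 4.3.3 on log2 of FPKM plus 0.1, in 1 fit of 12 libraries with 8 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. Contrasts were the knockdown under vehicle and dex, the dex response with each small interfering RNA, and the difference of the 2 responses. Libraries of a group correlated at 0.988 to 0.996. On simulated data with 200 changed genes and a dispersion of 0.01, between 83.3 and 91.0% of 2-fold changes and between 36.4 and 39.4% of changes of 0.5 on the log2 scale were recovered in the 4 simple contrasts, with 7 to 12 false calls. The simulated libraries were independent, with 1 dispersion for every gene, so these shares are not the power in the real data. For A549, whose pooled columns allow no test of replicates, the authors' log2 fold changes and FDR were used with 1 transcript per gene, the one with the highest mean reads, and differences between 2 responses are descriptions of list medians beside 10000 random lists matched in 20 expression bins (seed 1).

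Lists of genes were written before the data were examined: glucocorticoid receptor induced, TNF and NF-kB induced, interferon response, cholesterol synthesis, cell cycle, p53 target, YAP and TEAD target, mesenchymal and matrix, epithelial, unfolded protein and amino acid stress, hypoxia and glycolysis, and replication-dependent histone genes, the IRF2BP2 family with its partners and receptors, and markers of A549, of HEK293 and of blood, endothelial and fibroblast cells. Each of the 16 was tested with limma's camera (preset correlation 0.01, adjusted over the 16 lists of a contrast), and its called members were counted over all genes and adjusted over the list alone. NFKBIA is on 2 of these lists, the glucocorticoid receptor and the TNF list. Named genes followed a rule set at the same time: IRF2BP2 in every comparison; the 10 largest rises and falls with adjusted p under 0.05, a mean CPM of at least 5 in the higher group and no overlap between the libraries of the 2 groups (for the difference of responses no such condition), leaving out names of non-coding and antisense genes; up to 4 members with the smallest p per described list; and members of the glucocorticoid receptor and TNF lists in the difference of responses. For A549 the condition on overlap between libraries could not be applied, and the CPM was that of the pooled columns.

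Peaks were intersected with bedtools 2.31.1 (at least 1 base) and tied to genes with a start within 10 kb, a promoter being within 1 kb. Called and uncalled genes near peaks were compared with Fisher's exact test, two-sided, adjusted over 8 tests, and the lists over 32 tests. Calls were compared only between contrasts without a library in common. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and the R package data.table (version 1.17.8).

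Alternatives were median-of-ratios scaling, no filter, only the compared groups in the fit, a replicate block, each library left out in turn, a pseudocount of 1, voom on recovered reads, leaving out genes above 0.5 reads per base, every transcript as deposited, the FDR recomputed over 1 transcript per gene, ratios of pooled FPKM (pseudocount 0.01), an estimated correlation for camera, gene distances of 1 and 50 kb, an expression-matched background, and a reciprocal overlap of 50%. The authors' other A549 comparisons (both agents against vehicle and against dex) were not used here, and raw reads were not analysed here. The results of 1 gene are not reported here.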

Results

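The series measured how human cells with lowered IRF2BP2, a protein known as a transcriptional cofactor, answered to dexamethasone (dex), a synthetic glucocorticoid, and to tumour necrosis factor (TNF), an inflammatory cytokine. HEK293-GR cells are a kidney-derived line that constantly expresses the glucocorticoid receptor, and A549 is a lung adenocarcinoma line. Both lines received a small interfering RNA against IRF2BP2 (siIRF2BP2) or a non-targeting control (siNON) at 20 nM for 72 h. RNA was sequenced after 6 h of vehicle (ethanol) or 100 nM dex, and in A549 also after 10 ng/ml TNF or both agents together. The labels list 44 samples, of which 24 are A549 RNA samples in 8 groups of 3, 16 are HEK293-GR RNA samples in 4 groups of 4, and 4 are chromatin immunoprecipitations (ChIP) of IRF2BP2 in HEK293-GR cells. The HEK293-GR table held a column for 12 of the 16 RNA samples, 3 per group, at 18.2 to 28.5 M tags per library. The A549 table held 1 pooled column per group, at 35.8 to 56.9 M tags, so no spread between A549 replicates could be computed here. The study's description calls the replicates biological, while the sample labels do not say that each came from a separate culture, so they may be technical in part.

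IRF2BP2 itself was lower in every siIRF2BP2 library of HEK293-GR cells than in every siNON library. Under vehicle it stood at 22.9 ± 2.41 FPKM (mean ± SD, n = 3) with siNON and at 12.7 ± 0.960 FPKM (n = 3) with siIRF2BP2. Under dex the means were 20.0 ± 0.605 and 10.4 ± 0.752 FPKM (n = 3 each). The log2 fold change was -0.84 ± 0.08 (limma, ± SE, adjusted p = 1.87e-05) under vehicle and -0.94 ± 0.08 (adjusted p = 3.44e-06) under dex. The log2 fold change with dex was -0.19 ± 0.08 with siNON, which did not pass the limma threshold (adjusted p = 0.122), and -0.29 ± 0.08 with siIRF2BP2 (limma adjusted p = 0.037). The siNON change passed with median-of-ratios scaling (-0.23) and without siNON vehicle replicate 3 (-0.28, limma adjusted p = 0.0229). The siIRF2BP2 call was lost with a replicate block, without siIRF2BP2 vehicle replicate 1 or 3 and without siIRF2BP2 dex replicate 1 or 3, and the difference of the 2 responses was -0.10 ± 0.12 (limma adjusted p = 0.845). In A549 cells the authors' deposited table gave log2 fold changes of IRF2BP2 of -0.31 under vehicle, -0.66 under dex, -0.40 under TNF and -0.62 under both agents. The log2 ratios of the pooled FPKM were smaller, at -0.18, -0.45, -0.30 and -0.50 (from 29.7 to 26.3 FPKM under vehicle). In the authors' deposited table its dex response was 0.17 with siNON and -0.17 with siIRF2BP2, its TNF response -0.06 and -0.15, and its response to dex added to TNF -0.03 and -0.26, none past an FDR of 0.05. The gene lies on chromosome 1 from 234740015 to 234745271 on the minus strand (build hg19).

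**Figure D1:**
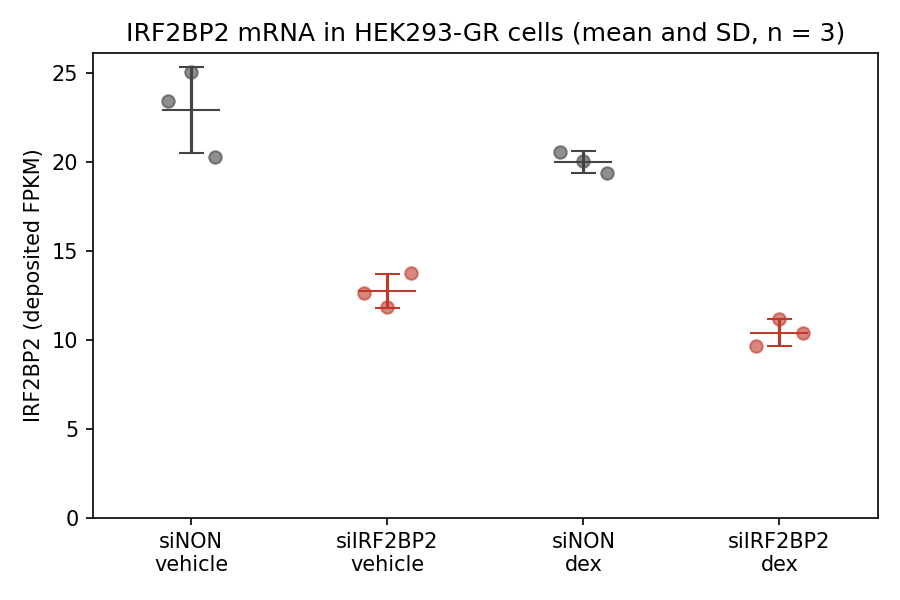
IRF2BP2 level in FPKM (y axis) in the 4 HEK293-GR groups (x axis), with a point per library and the mean ± SD of 3 libraries. The siIRF2BP2 libraries lie between 9.64 and 13.7 FPKM and the siNON libraries between 19.3 and 25.0 FPKM.

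The first comparison asked what lowering IRF2BP2 changed in HEK293-GR cells without hormone. MMP2, a matrix-degrading gelatinase, had the largest fall among the genes chosen by size, with a log2 fold change of -2.12 ± 0.16 (limma, ± SE, n = 3 libraries per group; from 2.80 ± 0.444 to 0.565 ± 0.07 FPKM). WT1, a transcription factor of kidney development, changed by -1.22 ± 0.14 and TGFA, a ligand of the epidermal growth factor receptor, by -1.18 ± 0.13. COL12A1, a fibril-associated collagen, rose by 1.33 ± 0.14, KRT17, a keratin, by 1.07 ± 0.12, and INHBE, an inhibin subunit, by 1.06 ± 0.16. Of 22 measured YAP and TEAD target genes, 11 rose and 1 fell, and adjusted over the list alone 12 rose and 1 fell. They included CTGF, a matricellular protein, at 1.03 ± 0.11, AMOTL2 at 0.83 ± 0.13, CYR61 at 0.59 ± 0.11 and LATS2, a Hippo pathway kinase, at 0.60 ± 0.12. The camera test placed this list above the other genes (adjusted p = 0.000721; adjusted p = 0.359 with an estimated correlation). Of 23 TNF and NF-kB induced genes, 4 rose and none fell (adjusted over the list alone 7 and 0), among them the chemokines CXCL8 at 1.93 ± 0.19 and CXCL2 at 1.66 ± 0.18, the cyclooxygenase PTGS2 at 0.78 ± 0.18 and the NF-kB inhibitor NFKBIA at 0.32 ± 0.08. Camera gave that list an adjusted p = 0.0332 (adjusted p = 0.359 with an estimated correlation). CXCL8 and CXCL2 rose by more than COL12A1 but were not among the genes chosen by size. They thus had a mean CPM under 5 or libraries that overlapped between the groups, so their folds are less certain. Of 18 unfolded protein and amino acid stress genes, 5 rose (adjusted over the list alone 6), including the chaperone DNAJB9 at 1.11 ± 0.13 and the transcription factor DDIT3 at 0.63 ± 0.10 (camera adjusted p = 0.0332; adjusted p = 0.778 with an estimated correlation). Of 27 glucocorticoid receptor induced genes, 6 rose and 1 fell (adjusted over the list alone 7 and 2; camera adjusted p = 0.356). Of 22 cholesterol synthesis genes, 5 fell and 1 rose (adjusted over the list alone 7 and 1), with LSS, the lanosterol synthase, at -0.59 ± 0.07, INSIG1 at -0.38 ± 0.07 and SREBF2, the transcription factor of the pathway, at -0.44 ± 0.09 (camera adjusted p = 0.000438; adjusted p = 0.359 with an estimated correlation). In all, limma called 2414 of 15593 genes, 1247 higher and 1167 lower, of which 37 and 45 changed by at least 1 on the log2 scale. The authors' deposited comparison called 313 higher and 530 lower. The count rested on single libraries: it was 4827 without siNON vehicle replicate 3, 1170 without siIRF2BP2 vehicle replicate 2, 1178 without siNON vehicle replicate 1 and 1348 without siNON vehicle replicate 2. With only the 2 groups compared in the fit it was 567. The SE rest on 1 spread over all 12 libraries. In the median gene siNON vehicle libraries lay 0.128 to 0.188 from the rest of their group on the log2 scale. The siIRF2BP2 vehicle libraries lay 0.0934 to 0.146 away. Under dex the values were 0.0693 to 0.0822 with siNON and 0.0874 to 0.111 with siIRF2BP2. The shared spread can thus make SE and p-values under vehicle too small. The camera results moved as well, with between 1 and 5 lists past the threshold when single libraries were left out.

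Under dex, the knockdown changed MMP2 by -2.46 ± 0.16 (± SE, n = 3 per group), WT1 by -1.51 ± 0.14, the calcium sensor NCS1 by -1.46 ± 0.09 and GPER1, a membrane estrogen receptor, by -1.27 ± 0.15. CTGF rose by 1.38 ± 0.11, SLC7A11, the cystine transporter, by 1.38 ± 0.22, CREB5, a transcription factor, by 1.37 ± 0.11 and SEMA3C, a semaphorin, by 1.21 ± 0.15. Of the 22 cholesterol synthesis genes, 11 fell and 2 rose (adjusted over the list alone 11 and 2), including LSS at -0.75 ± 0.07, INSIG1 at -0.75 ± 0.07 and MVD at -0.69 ± 0.10 (camera adjusted p = 0.000409; adjusted p = 0.809 with an estimated correlation). The other 15 lists did not pass camera. Among these, 10 of 22 YAP and TEAD target genes rose and 1 fell, 6 of 20 p53 target genes fell and 2 rose, with PHLDA3 at -0.61 ± 0.09 and FDXR at -0.48 ± 0.09, and 5 of 19 interferon response genes rose and 1 fell. Adjusted over the list alone, 11 and 1, 2 and 6, and 3 and 1 of these rose and fell. Of 27 glucocorticoid receptor induced genes 3 rose and 6 fell (adjusted over the list alone 3 and 6). The replication-dependent histone genes held 4 of 9 that rose and 1 that fell (adjusted over the list alone 4 and 1), and the blood, endothelial and fibroblast cell markers 1 of 7 that rose, CD14 at 1.15 ± 0.30, and 1 that fell, HBA1 at -0.89 ± 0.26 (adjusted over the list alone 1 and 1). Limma called 6188 genes, 3486 higher and 2702 lower, of which 121 and 83 changed by at least 1 on the log2 scale. With only the 2 groups compared in the fit it called 7852. The authors' deposited comparison called 3469 higher and 3787 lower. The calls under vehicle and under dex shared 969 higher and 1052 lower genes, where 278.8 and 202.2 were expected from the counts, and 99.9% of the genes called in both had the same sign.

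The dex response with siNON asked what the hormone did in control cells. Of 27 measured glucocorticoid receptor induced genes, 25 rose and none fell (adjusted over the list alone 26 and 0), with a median log2 fold change of 1.29. The kinase SGK1 rose by 3.69 ± 0.09 (± SE, n = 3 per group), PDK4, a regulator of pyruvate use, by 4.37 ± 0.12 and NFKBIA by 1.83 ± 0.08. Camera kept this list with the preset correlation (adjusted p = 3.90e-31) and with an estimated one (adjusted p = 0.00803 with an estimated correlation). RASD1, a small GTPase, went from 0.432 ± 0.0736 to 28.7 ± 1.18 FPKM (mean ± SD, n = 3), and S100P, a calcium-binding protein, from 1.19 ± 0.546 to 72.6 ± 2.84 FPKM. The densest gene had 2.83 to 3.11 reads per base across the libraries, and if this common level is a limit, the values and folds of dense genes such as S100P under dex are understated. The near-identical tubulin genes TUBA3D and TUBA3E, whose reads cannot be told apart with certainty, stood close to 0 under vehicle (0.009 ± 0.0156 FPKM for TUBA3D) and at 8.71 ± 0.543 FPKM for TUBA3D under dex. Dex changed ZNF711 by -2.22 ± 0.11, the inhibitor of DNA binding ID4 by -2.07 ± 0.10, the protease ADAMTS1 by -1.98 ± 0.08 and the growth factor FGF9 by -1.80 ± 0.13. Of 13 HEK293 cell markers 5 fell (adjusted over the list alone 5), with the developmental transcription factors ZIC2 at -0.66 ± 0.08 and HOXA11 at -0.61 ± 0.08 (camera adjusted p = 0.00168; adjusted p = 0.0388 with an estimated correlation). Of 19 mesenchymal and matrix genes 6 rose (adjusted over the list alone 6), including THBS1 at 1.53 ± 0.16 and SNAI2 at 1.66 ± 0.19 (camera adjusted p = 0.0442; adjusted p = 0.538 with an estimated correlation). Among lists that did not pass camera, 3 of 23 TNF and NF-kB induced genes rose and 4 fell (adjusted over the list alone 4 and 4), with TNFAIP3 at 1.06 ± 0.11 and CXCL8 at -0.94 ± 0.19, and 4 of 18 hypoxia and glycolysis genes rose and 1 fell (adjusted over the list alone 5 and 2), with the glucose transporter SLC2A3 at 2.46 ± 0.08. Nor did the YAP and TEAD target genes pass, of which 10 of 22 fell and 3 rose (adjusted over the list alone 10 and 3; camera adjusted p = 0.0510), or the epithelial genes, of which 6 of 17 fell (adjusted over the list alone 6, with 1 that rose; camera adjusted p = 0.0811). Of 20 p53 target genes 8 rose and 2 fell (adjusted over the list alone 9 and 2), and this list did not pass either (camera adjusted p = 0.118). Limma called 3235 genes, 1704 higher and 1531 lower, and the count was 1978 without siNON dex replicate 3.

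With siIRF2BP2, dex raised 25 of the 27 glucocorticoid receptor induced genes and lowered none (adjusted over the list alone 26 and 0), with a median of 0.97. PDK4 rose by 4.45 ± 0.12 (± SE, n = 3 per group), SGK1 by 3.10 ± 0.09, the cell cycle inhibitor CDKN1C by 4.37 ± 0.18 and the clock gene PER1 by 2.20 ± 0.11. Camera gave the list an adjusted p = 9.73e-41 (adjusted p = 0.00321 with an estimated correlation). Dex changed ADAMTS1 by -1.86 ± 0.08, the netrin receptor UNC5B by -1.72 ± 0.12 and IGFBP5 by -1.55 ± 0.10. The HEK293 cell markers fell in 4 of 13 members (adjusted over the list alone 5; camera adjusted p = 0.000211; adjusted p = 0.0190 with an estimated correlation). Of 22 YAP and TEAD target genes 8 fell and 2 rose (adjusted over the list alone 8 and 2), the risers being the coagulation factor F3 at 2.48 ± 0.08 and CTGF at 1.10 ± 0.11 (camera adjusted p = 0.00215; adjusted p = 0.582 with an estimated correlation). Of 22 cholesterol synthesis genes 6 fell and 1 rose (adjusted over the list alone 6 and 1), with INSIG1 at -0.66 ± 0.07 and the riser NSDHL at 0.71 ± 0.08 (camera adjusted p = 0.0395; adjusted p = 0.668 with an estimated correlation). Of 17 epithelial genes 4 fell (adjusted over the list alone 5), including KRT19 at -0.52 ± 0.09 (camera adjusted p = 0.0278; adjusted p = 0.668 with an estimated correlation). The A549 cell markers passed camera on 1 called gene of 4, S100P at 4.30 ± 0.21 (adjusted p = 0.0278; adjusted p = 0.157 with an estimated correlation; adjusted over the list alone 1). None of the 25 cell cycle genes was called by limma over all genes or adjusted over the list alone, and the smallest adjusted p was that of BUB1B at -0.13 ± 0.08 (0.422). Limma called 1630 genes, 914 higher and 716 lower, and 803 of the higher and 573 of the lower genes were also called with siNON, where 99.9 and 70.3 were expected.

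The difference of the 2 dex responses asked whether the knockdown changed the hormone response in HEK293-GR cells. Limma called 2 of 15593 genes, both with a smaller rise after knockdown: PDGFA, a platelet-derived growth factor, at -1.30 ± 0.19 (± SE, n = 3 per group, adjusted p = 0.0358) and SLC2A3 at -0.79 ± 0.12 (adjusted p = 0.0358). An unadjusted p under 0.05 was reached by 805 genes. In the same limma fit, among the glucocorticoid receptor induced genes, SGK1 differed by -0.59 ± 0.13 (adjusted p = 0.262), CRISPLD2 by -0.92 ± 0.26 (adjusted p = 0.513) and NFKBIA by -0.49 ± 0.11 (adjusted p = 0.302), none past the threshold over all genes. Adjusted over the list alone, 5 of its 27 genes were lower, and the list's median difference was -0.14 (camera adjusted p = 9.57e-05; adjusted p = 0.516 with an estimated correlation). The TNF and NF-kB induced genes had a median difference of -0.17, with 2 of 23 lower adjusted over the list alone, and CXCL2 at -0.92 ± 0.25 and CXCL8 at -0.81 ± 0.27 (camera adjusted p = 0.0137; adjusted p = 0.516 with an estimated correlation). The cholesterol synthesis genes had a median of -0.09 (2 lower adjusted over the list alone; camera adjusted p = 0.0341; adjusted p = 0.785 with an estimated correlation) and the mesenchymal and matrix genes one of -0.18 (0 adjusted over the list alone; camera adjusted p = 0.0341; adjusted p = 0.819 with an estimated correlation). With a replicate block 0 genes were called, with a pseudocount of 1 22 genes, and without single libraries between 0 and 6. In simulated libraries of this size 76.1% of 2-fold differences between responses were recovered, and 4.55% of those of 0.5 on the log2 scale. The simulation drew independent libraries with 1 dispersion of 0.01 for every gene. It holds none of the shared variation between the real libraries, so these shares are not the power of the test in these data.

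In A549 cells the knockdown was compared under each of the 4 treatments, from the authors' deposited table. EGR1, an immediate early transcription factor, had the largest fall among the named genes under vehicle, with a log2 fold change of -4.60 (from 28.6 to 1.29 pooled FPKM), and also fell under dex (-4.41), TNF (-5.22) and both agents (-4.08). PTGS2 changed by -3.59 under dex in the authors' deposited table, from 106 to 10.6 pooled FPKM, and by -2.69, -2.59 and -2.50 under vehicle, TNF and both. The fibrinogen chains FGG and FGA rose under vehicle by 1.77 and 1.64, and AGT, the angiotensin precursor, by 1.85 under vehicle and 2.46 under dex. Under TNF the authors' deposited table listed rises of the hexokinase HK2 by 2.59, the chemokine CXCL10 by 2.35 and the complement factor CFB by 1.93, and under both agents of CXCL10 by 2.54 and of LBP, a lipopolysaccharide-binding protein, by 2.38. IGF2 and INS-IGF2, which overlap and share reads, both changed by -3.11 under vehicle.

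The cholesterol synthesis genes were lower with siIRF2BP2 under every treatment in A549, with 19, 18, 16 and 16 of 22 called lower and 0, 0, 1 and 1 higher by the authors' FDR under vehicle, dex, TNF and both, and medians of -0.56, -0.51, -0.53 and -0.57. INSIG1 changed by -2.07 under vehicle (FDR = 5.06e-119) and HMGCS1, a synthase of the mevalonate pathway, by -1.22. Of the 28 glucocorticoid receptor induced genes 13, 13, 13 and 14 were lower and 1, 5, 4 and 3 higher in the authors' deposited table (medians -0.33, -0.31, -0.23 and -0.39), including PER1 at -2.12 and the leucine zipper protein TSC22D3 at -1.40 under vehicle. Of 22 YAP and TEAD target genes 10, 11, 11 and 7 were lower and 2, 5, 6 and 7 higher (medians -0.17, -0.24, -0.24 and -0.12). Of 32 TNF and NF-kB induced genes 12, 13, 12 and 7 were lower and 3, 4, 9 and 12 higher (medians -0.15, -0.08, -0.05 and 0.07). Of 11 replication-dependent histone genes 1, 0, 1 and 0 were lower and 1, 2, 2 and 2 higher (medians -0.49, 0.09, 0.04 and -0.12). The interferon response genes were higher in 7, 11, 23 and 14 and lower in 2, 1, 0 and 1 of 26 members (medians 0.25, 0.47, 0.84 and 0.73), with the guanylate-binding protein GBP1 at 1.41 and the RNA sensor IFIH1 at 0.88 under TNF. Of 18 hypoxia and glycolysis genes 4, 4, 10 and 9 were higher and 4, 3, 2 and 3 lower (medians -0.15, 0.02, 0.47 and 0.25). Under TNF PFKFB4 was at 1.79 and PDK1 at 1.04. Of 20 p53 target genes 10, 10, 8 and 6 were lower and 3, 3, 6 and 6 higher under vehicle, dex, TNF and both. Under vehicle the cytokine GDF15 was at -1.82. Of 17 epithelial genes 6, 3, 6 and 7 were lower and 0, 1, 4 and 4 higher. Under vehicle the keratins were lower, KRT19 at -1.10 and KRT18 at -0.79. The A549 cell markers were lower in 6, 7, 7 and 7 and higher in 3, 0, 2 and 2 of 13. Under vehicle the aldehyde dehydrogenase ALDH3A1 was at -1.50 and AKR1C1 at 0.71. Of 18 genes of the IRF2BP2 family, partners and receptors 8, 7, 8 and 8 were higher and 3, 3, 4 and 2 lower. Under vehicle the coactivator NCOA3 was at -0.78 and VGLL4 at 0.65. By the authors' FDR, 5758, 5318, 6509 and 6015 of 25689 genes passed 0.05 in the authors' deposited table under vehicle, dex, TNF and both. List members were counted among the 15607 genes with at least 10 mean reads. Of these, 2692, 2532, 3270 and 2972 were called higher and 3009, 2741, 3187 and 2994 lower, the background for the list counts. Ratios of the pooled FPKM lay 0.121 above the authors' log2 fold changes in the median under vehicle and 0.128 above under dex, so directions are given relative to the authors' scale.

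**Figure D2:**
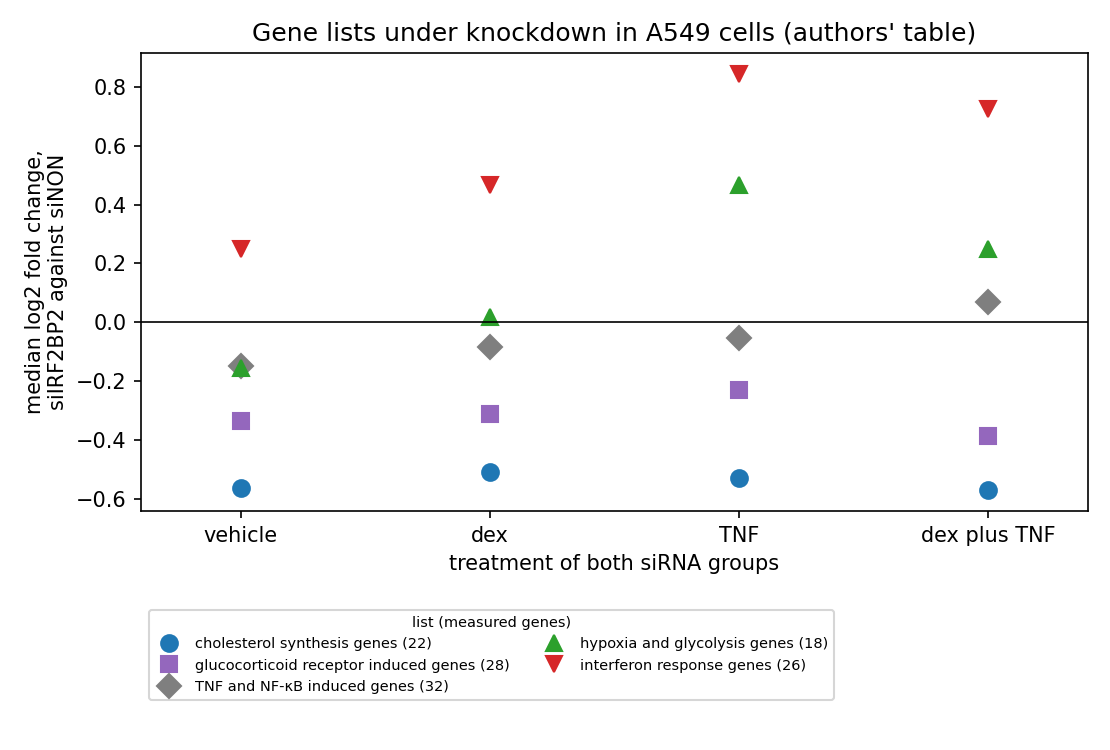
Median log2 fold change of siIRF2BP2 over siNON (y axis) in the authors' deposited A549 table for 5 gene lists under the 4 treatments (x axis). The cholesterol synthesis genes lie between -0.57 and -0.51 and the interferon response genes between 0.25 and 0.84.

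The A549 dex response was also read from the authors' deposited table. Of the 28 glucocorticoid receptor induced genes 27 rose and 1 fell with siNON (median 2.08) and 27 rose with siIRF2BP2 (median 2.04). FKBP5, a co-chaperone of the receptor, rose by 4.11 with siNON and by 4.07 with siIRF2BP2, and the transcription factor TFCP2L1 by 4.27 and 4.70. Of 32 TNF and NF-kB induced genes 12 fell and 3 rose with siNON (median -0.67), among them the chemokines CXCL1 at -2.08 and CXCL3 at -2.07, and 15 fell and 7 rose with siIRF2BP2 (median -0.64), with CXCL5 at -1.33. Of 22 YAP and TEAD target genes 10 rose with siNON, including ANKRD1 at 1.56, and 12 with siIRF2BP2, including AMOTL2 at 1.54, while 1 and 2 fell. Of 25 cell cycle genes 1 fell with siNON and 10 with siIRF2BP2. The authors' FDR called small changes less often with siNON. Among genes with at least 1000 mean reads and changes of 0.3 to 0.5 it called 53.3% with siNON and 98.9% with siIRF2BP2. Counts of called list members are therefore no measure of a difference between the 2 responses. The authors' deposited table called 1785 genes with siNON and 4034 with siIRF2BP2, of which 905 higher and 568 lower genes were called in both. No test of the difference between the 2 responses could be made from pooled values.

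TNF raised all 32 measured TNF and NF-kB induced genes in A549 with either small interfering RNA, by a median of 3.07 with siNON, in the authors' deposited table. The adhesion molecule ICAM1 rose by 7.71 with siNON (from 0.208 to 40.9 pooled FPKM) and by 7.23 with siIRF2BP2, the chemokine CCL20 by 6.88 and 8.37, and TNFAIP3 by 3.96 with siNON. Of 26 interferon response genes 23 rose with siNON and 25 with siIRF2BP2 (medians 2.84 and 2.71), with GBP1 at 6.49 and 7.54. Of 18 hypoxia and glycolysis genes 12 fell and 0 rose with siNON (median -0.46), including the carbonic anhydrase CA9 at -1.71, while 7 fell and 4 rose with siIRF2BP2 (median -0.10), including ADM at 0.81. NOD2 and CXCL10 were listed at 0 in the siIRF2BP2 vehicle group, so no fold is given for them there. The authors' deposited table called 3279 genes with siNON and 6303 with siIRF2BP2, and 1536 higher and 1220 lower genes were called in both. Whether small TNF changes were called alike with both was not examined, so the list counts do not measure a difference.

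Adding dex to TNF lowered 23 of the 32 TNF and NF-kB induced genes with siNON (median -0.87) and 21 with siIRF2BP2 (median -0.59) in the authors' deposited table, while 5 and 7 rose. The adhesion molecule VCAM1 changed by -3.81 and -4.43, the chemokine CCL2 by -1.96 and -1.86, and the cytokine subunit IL23A by -3.71 and -4.65. Of 26 interferon response genes 20 and 23 fell (medians -1.06 and -1.12), with the antiviral GTPase MX1 at -2.47 and -2.21. Of 28 glucocorticoid receptor induced genes 26 and 25 rose. Of 25 cell cycle genes 2 fell with siNON and 19 with siIRF2BP2 (medians -0.09 and -0.32), including the replication factor CDC6 at -0.29 and -0.91. The table called 2809 and 4122 genes. Calling of small changes was not compared between the 2 here either, so the counts of called members alone show no difference. Genes raised at least 2-fold by TNF were picked in one arm and read in the other: 298 of 756 (39.4%) were lowered by dex with siNON and 248 of 502 (49.4%) with siIRF2BP2, and since the sets differ, the 2 shares were not tested against each other.

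The differences between the A549 responses with siIRF2BP2 and with siNON have no replicate check, and each list median is set beside 10000 random lists of its size matched on expression, as a description of these libraries. The random lists were not matched on the size of the response. A list chosen for large responses can therefore lie outside their range through scatter alone, so its percentile on its own is no sign of a change. For the TNF response all 18 hypoxia and glycolysis genes had a higher log2 fold change with siIRF2BP2 (median difference 0.45), and the interferon response genes had a median of 0.50 with 22 of 26 above 0, both at percentile 100. The replication-dependent histone genes had a median of 0.34 with 10 of 11 above 0 (percentile 98.9), and the YAP and TEAD target genes had one of 0.16. The TNF and NF-kB induced genes had a median of 0.21 (0.40 over every transcript) and the glucocorticoid receptor induced genes one of -0.13. For dex the glucocorticoid receptor induced genes, a list of large dex responses, had a median of 0.19 with 16 of 28 above 0 and 12 below. Their percentile of 100 cannot decide on a difference for that reason, and their median response was no higher with siIRF2BP2 than with siNON. In that comparison the replication-dependent histone genes had a median of 0.27 with 10 of 11 above 0, the YAP and TEAD target genes one of 0.20, and the TNF and NF-kB induced genes one of 0.0750 (0.0220 with ratios of pooled FPKM). For dex added to TNF, all 25 cell cycle genes were lower with siIRF2BP2 (median -0.24, percentile 0), and the TNF and NF-kB induced genes had a median of 0.11 (percentile 99.8; 0.0445 over every transcript). The hypoxia and glycolysis genes had a median of -0.18 with 14 of 18 below 0 (percentile 0), and the interferon response genes one of -0.14 with 15 of 26 below 0. The glucocorticoid receptor induced genes had one of 0.0869 (0.0037 over every transcript). Within siNON, the dex response under TNF less that under vehicle had a median of -0.77 in the interferon response genes and -0.18 in the TNF and NF-kB induced genes (-0.11 over every transcript). In the glucocorticoid receptor induced genes it was -0.16 (-0.0867 with ratios of pooled FPKM).

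Across the 2 cell lines, the knockdown under vehicle raised 456 genes and lowered 588 genes in both, where 204 and 218 were expected (Fisher's exact test, p = 3.70e-75 and 1.74e-149), and 88.3% of the 1182 genes called in both had the same sign. The YAP and TEAD target genes rose in 11 and fell in 1 of 22 in HEK293-GR cells, and were higher in 2 and lower in 10 of 22 in the authors' deposited table for A549. CXCL8 of the TNF and NF-kB list (4 higher and 0 lower in HEK293-GR cells, 3 higher and 12 lower in the A549 table) rose by 1.93 ± 0.19 in HEK293-GR cells (limma, n = 3 per group) and was at -2.55 in the authors' deposited table for A549. In HEK293-GR cells CXCL8 missed the condition on CPM or on overlap for genes chosen by size, so its fold there is less certain. CTGF of the YAP and TEAD list rose by 1.03 ± 0.11 in HEK293-GR cells and was at -0.79 in the authors' deposited table for A549, and the differences between the cell lines were not tested. LSS and INSIG1 of cholesterol synthesis fell in HEK293-GR cells, and INSIG1 was at -2.07 in the authors' deposited table for A549. Under dex the same sign was found in 74.9% of 2215 genes called in both. For the dex response with siNON 289 higher and 164 lower genes were shared (2.86 and 2.78 times the number expected), with the same sign in 72.7% of 623. The measures of the 2 lines were unlike. A549 values used the genomic span in 98.9% of transcripts and the authors' FDR, and HEK293-GR values used the exon length and limma. The expected numbers were not matched on expression.

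ChIP of IRF2BP2 in HEK293-GR cells, after 1 h of vehicle or dex with 2 replicates each, was deposited as 1 peak list per condition. The vehicle list held 1108 peaks and the dex list 1400, and 484 overlapped, which is 43.7% of the vehicle and 34.6% of the dex list. Of the 27 glucocorticoid receptor induced genes 8 had a dex peak within 10 kb of their start, against 1.62% of other genes (Fisher's exact test, adjusted p = 2.90e-07 over 32 tests): BCL6, DUSP1, IGFBP1, KLF15, PDK4, PER1, SLC19A2 and TFCP2L1, named after their places were seen. A vehicle peak lay near 2 of the 27, which did not pass (Fisher's exact test, adjusted p = 0.244). The PER1 peak lay on chromosome 17 from 8057660 to 8057991 and that of PDK4 on chromosome 7 from 95226397 to 95226728, both in the dex list alone. Of the 22 YAP and TEAD target genes 6 had a vehicle peak (Fisher's exact test, adjusted p = 1.02e-05). A dex peak lay near 3 of them, which did not pass (Fisher's exact test, adjusted p = 0.0595). Peaks in both lists lay at the promoters of AMOTL2 (chromosome 3, 134093152 to 134093494) and TEAD1 (chromosome 11, 12695814 to 12696156). IRF2BP2 had 2 vehicle peaks of its own, from 234743081 to 234743423 in the gene body and from 234744736 to 234745078 at the promoter. Genes higher after knockdown under vehicle were near a vehicle peak more often than genes not called, 39 of 1247 against 177 of 13179 (odds ratio 2.37, Fisher's exact test, two-sided, adjusted p = 1.99e-05 over 8 tests), and genes lower had a ratio that did not pass (odds ratio 1.09, adjusted p = 0.692). With single libraries left out the ratio ranged from 1.68 to 3.61 for higher and from 0.69 to 1.28 for lower genes. With gene starts within 1 kb it was 2.92 for higher genes (Fisher's exact test, adjusted p = 0.000553), and within 50 kb it was 1.34 (adjusted p = 0.0307). Under dex the odds ratios for the knockdown were 1.16 for higher and 1.19 for lower genes (Fisher's exact test, adjusted p = 0.397 for both). Genes raised by dex with siNON were near a dex peak with an odds ratio of 4.83 (Fisher's exact test, adjusted p = 1.53e-23) and genes lowered with one of 2.59 (adjusted p = 2.14e-06), and with siIRF2BP2 the ratios were 5.53 (adjusted p = 5.48e-21) and 3.38 (adjusted p = 4.03e-07). These ratios also depended on the distance: within 1 kb and 50 kb they were 7.96 and 2.57 for genes raised and 4.40 and 1.76 for genes lowered with siNON. With siIRF2BP2 they were 6.71 and 3.33 for genes raised and 5.33 and 2.52 for genes lowered. Of all 15593 tested genes 1531 fell with dex in siNON cells. Near peaks of the dex list alone 8 of 149 genes (5.37%) fell, against 34 of 113 (30.1%) near peaks of both lists. Near peaks of the vehicle list alone 35 of 123 (28.5%) fell. The excess of lowered genes near dex peaks thus lay at peaks also found under vehicle. The peak lists carry no depth or usable score, so the precision behind a single peak is unknown.

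**Figure D3:**
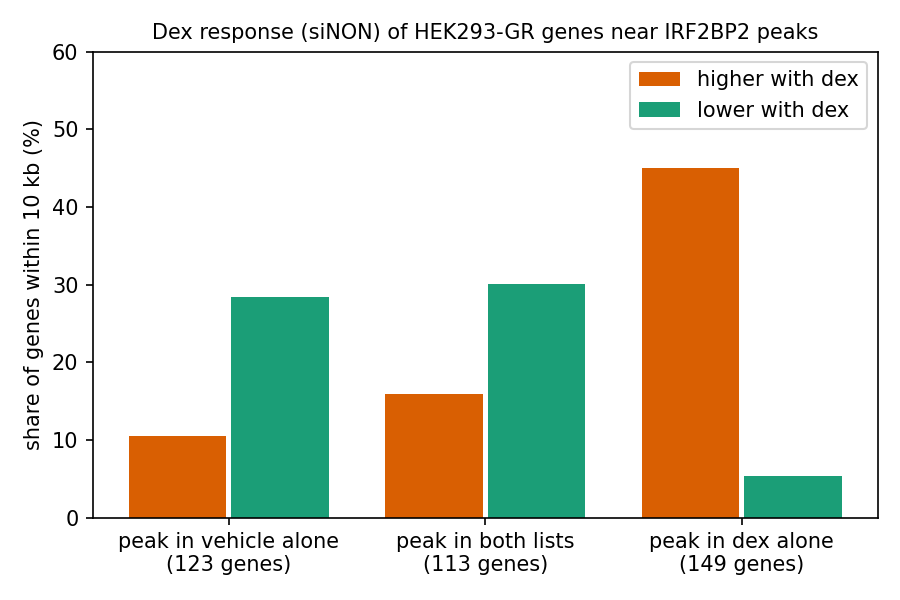
Percent of tested genes within 10 kb of a peak (y axis) that were higher or lower with dex in siNON HEK293-GR cells, as bars for peaks in the vehicle list alone, in both lists and in the dex list alone (x axis). Near peaks of the dex list alone 45.0% of 149 genes were higher and 5.37% lower, and near peaks of both lists 15.9% and 30.1% of 113.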

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

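All tests of explanations in this part, the splits of the libraries included, were chosen after the results they measure had been seen. The dex response of HEK293-GR cells differed between siIRF2BP2 and siNON by a test of the difference itself for the glucose transporter SLC2A3 (-0.79 on the log2 scale) and the growth factor PDGFA (-1.30), each with limma adjusted p = 0.0358 and n = 3 per group. The same test set apart the glucocorticoid receptor induced genes (median -0.14), the TNF and NF-kB induced genes (-0.17), the cholesterol synthesis genes (-0.0895) and the mesenchymal and matrix genes (-0.18) by camera. None of these lists passed with an estimated correlation, where their adjusted p ranged from 0.516 to 0.819. Splits of all libraries carry the knockdown and dex effects into the difference, the one with most calls (78 genes) 1.33 times the knockdown effect, so the 3 of 100 splits with at least the 2 real calls do not decide whether chance can be excluded. With both effects taken out before the splits, 4 of 100, the real one included, gave at least 2 calls, a share under 0.05, but the highest other split called 270 genes, which points to a structure of the samples beside the groups. Without single libraries the count ranged from 0 to 6, and it was 0 with a replicate block and without genes above 0.5 reads per base, so chance is not taken as excluded for these 2 genes.

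In HEK293-GR cells the knockdown called fewer genes under vehicle (2414) than under dex (6188). A swap of labels between siNON vehicle replicate 3 and a siIRF2BP2 vehicle library is argued against by an IRF2BP2 level of 20.3 FPKM in that replicate, since no siIRF2BP2 vehicle library exceeded 13.7 FPKM. A limit on reads per base as the whole cause is argued against as well, since without genes above 0.5 reads per base 2278 genes were called under vehicle and 5501 under dex, 2.41 times as many. Leaving out siNON vehicle replicate 3 raised the vehicle count to 4827, and its deviation from its group correlated with the knockdown effect under dex (r = 0.59, slope 0.50), but so did that of siIRF2BP2 vehicle replicate 2 (r = 0.56, slope 0.38; 1170 calls without it), so a shift of siNON vehicle replicate 3 alone cannot be told apart from a variation common to the vehicle libraries of both groups. A larger effect under dex stays open too. Called changes of at least 1 on the log2 scale numbered 37 higher and 45 lower under vehicle, and 121 and 83 under dex. The difference test above called 2 genes. In simulated libraries it recovered 4.55% of differences of 0.5 on that scale. Those libraries lack the shared variation of the real ones, so this share is not the power of the test here.

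For the dex response of A549 cells the authors' FDR called 4034 genes with siIRF2BP2 and 1785 with siNON. Deeper sequencing is argued against, since the siIRF2BP2 groups had 73.5 M pooled tags and the siNON groups 113.7 M. The next comparisons used the 7801 genes with at least 1000 mean reads (deep genes). Larger changes do not account for the counts, since the number of deep genes with an absolute log2 change of at least 1 was only 1.32 times as high (257 against 195). At changes of 0.3 to 0.5 on the log2 scale the authors' FDR called 45.5 percentage points more deep genes with siIRF2BP2 (98.9% of 697 against 53.3% of 587), so a larger spread between the siNON replicates in the authors' test may lie behind the counts. The A549 columns used here pool the replicates, so this was not tested directly, and a biological difference stays open.

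IRF2BP2 had a log2 fold change of -0.31 in A549 under vehicle in the authors' deposited table (-0.18 as a ratio of pooled FPKM, a scale that lies 0.121 higher in the median gene), beside 5758 called genes. Introns make up 11.4% of the counted span. Read at the density of the exons and unchanged by the knockdown, they would turn the fall of -0.84 seen in HEK293-GR cells into -0.72. That lies below -0.31, but it cannot decide on introns as the whole cause. The value takes over the fall of HEK293-GR cells and holds only if introns are no denser in reads than the exons. The fall of the exons alone was not measured in A549. Under dex, TNF and both agents the authors' deposited table gave -0.66, -0.40 and -0.62 for A549. Effects of the small interfering RNA through other genes cannot be told apart from those of IRF2BP2, since a single pool was used in both lines, where 88.3% of the genes called in both had the same sign.

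For the 4 simple HEK293-GR contrasts 3 against 3 libraries make 10 splits, which are too few for a share under 0.05, and in each 1 split, the real one, gave as many calls. The real counts and the highest of the other splits were 2414 and 1005 for the knockdown under vehicle, 6188 and 0 under dex, 3235 and 0 for dex with siNON, and 1630 and 1 for dex with siIRF2BP2.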

How the results depend on the processing

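The alternatives with a pseudocount of 1, voom, dense genes left out, a recomputed FDR and pooled ratios were chosen after the data had been seen, and the others before. Of 417 HEK293-GR gene results 294 were kept in every alternative run for single genes. Over those alternatives 4051 comparisons kept their side of the threshold, 546 lost it and none reversed. The fits without a filter, with every transcript or without dense genes were not among them. Of 200 A549 gene results 198 kept their side, 2 lost it and none reversed. Their only alternative was the median over every transcript of the gene in the same comparison. Such transcripts share reads, so this was a weak check. With only the compared groups in the fit the knockdown count went from 2414 to 567 under vehicle and from 6188 to 7852 under dex. For the dex response it went from 3235 to 2569 with siNON and from 1630 to 1791 with siIRF2BP2. These fits hold the same number of libraries, so fewer libraries alone do not account for the fall under vehicle. The siNON vehicle libraries varied more within their group than the dex libraries did, by the values given with the first comparison. The difference of the dex responses went from 2 calls to 0 with a replicate block, 22 with a pseudocount of 1 and 0 with genes above 0.5 reads per base left out. With every transcript as deposited the A549 counts, which then count transcripts, were 12848, 11868, 14550 and 13355 for the knockdown under vehicle, dex, TNF and both, 4004 and 9020 for dex, 7110 and 13941 for TNF, and 6324 and 9408 for dex added to TNF (siNON, siIRF2BP2). The A549 list medians changed as follows for every transcript and for pooled ratios: dex difference, receptor genes 0.18 and 0.13, TNF genes 0.0220 (ratios); TNF difference, receptor genes -0.16 (transcripts), TNF genes 0.40 and 0.20; dex added to TNF, receptor genes 0.0037 and 0.0471, TNF genes 0.0445 and 0.12; dex by TNF with siNON, receptor genes -0.11 and -0.0867, TNF genes -0.11 and -0.21. With an estimated correlation 0 lists passed for the knockdown under vehicle, 0 under dex, 2 for dex with siIRF2BP2 and 0 for the difference. The dex change of IRF2BP2 with siNON passed with median-of-ratios scaling (-0.23), and that with siIRF2BP2 did not pass with a replicate block (-0.29). For these changes the cause was not tested. Leaving out single libraries gave 1170 to 4827 calls for the knockdown under vehicle (siIRF2BP2 replicate 2 and siNON replicate 3; 1178 and 1348 without siNON replicates 1 and 2), 4149 to 5371 under dex, 1978 to 3927 for dex with siNON (siNON dex replicate 3 and siNON vehicle replicate 1), 1249 to 1489 with siIRF2BP2 and 0 to 6 for the difference: 6 and 5 without siNON vehicle replicates 1 and 2, 1 without siIRF2BP2 vehicle replicate 1, and 0 without siIRF2BP2 vehicle replicate 3 or any dex library. A group left with 2 libraries is assumed to vary like the others. Lists past camera ranged from 1 (without siNON vehicle replicate 3; 2 without siIRF2BP2 replicate 1) to 5 for the knockdown under vehicle, and for the difference from 1 (without siNON dex replicate 2 or siIRF2BP2 vehicle replicate 2; 2 without siIRF2BP2 vehicle replicate 3) to 4. The IRF2BP2 change with dex ranged from -0.28 (without siNON vehicle replicate 3, where it passed, adjusted p = 0.0229 by limma) to -0.13 with siNON and from -0.34 to -0.23 with siIRF2BP2, where it did not pass without vehicle replicates 1 or 3 or dex replicates 1 or 3. The odds ratio of genes raised by the knockdown near vehicle peaks ranged from 1.68 to 3.61 (without siNON vehicle replicate 1). With the replicate number as a block the 5 HEK293-GR counts were 1887, 5480, 2628, 1450 and 0, and the numbers did not pair the libraries: 4 of 18 same-number pairs had r over 0.1 (range -0.377 to 0.261), and 2 of 12 libraries were closest to their own number. No paired analysis was possible for A549 because its replicates are pooled, and neither were the filter, scaling, block and leave-one-out alternatives for it. DESeq2 was not run, since the values used are FPKM, nor a subset of stronger peaks by score, since the score is constant.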

Other observations

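The test in this part was chosen after the results had been seen. In HEK293-GR cells with siNON, 67 of 147 tested genes near peaks of the dex list alone rose with dex (45.6%), against 18 of 111 near peaks of both lists (16.2%; odds ratio 4.33, Fisher's exact test, two-sided, p = 5.63e-07). Genes near both kinds of peak were left out of that test. Of all 15593 tested genes 1704 rose, and near peaks of the vehicle list alone 13 of 123 (10.6%). Falls went the other way, with 8 of 149 near peaks of the dex list alone and 34 of 113 near peaks of both lists, which was not tested.

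In the HEK293-GR libraries 196 genes had over 1.5 reads per base. In the deepest library (28.5 M tags), siIRF2BP2 dex replicate 3, these genes lay a median of 0.30 below the mean of all libraries on the log2 scale. The medians ranged from -0.0313 to 0.165 with siNON and from -0.150 to 0.0322 with siIRF2BP2 under vehicle. Under dex they ranged from 0.0572 to 0.110 with siNON and from -0.303 to 0.170 with siIRF2BP2. The gene list tests were not rerun without dense genes. The authors' deposited HEK293-GR comparisons called 843 genes for the knockdown under vehicle (313 higher, 530 lower), 7256 under dex (3469 and 3787), 2578 for dex with siNON (1209 and 1369) and 1644 with siIRF2BP2 (819 and 825), of which limma also called 839, 5652, 2379 and 1419.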
